A study of Dunaliella tertiolecta with 6 samples.

How the data were processed

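RNA was measured in 6 libraries of Dunaliella tertiolecta UTEX LB 999, 3 without added iron and 3 with 1.5 µM added iron, and samples were grouped by the iron level in their labels. The deposited values are FPKM per gene in each library, made by the authors from 50 nt single-end reads of poly(A)-selected RNA, per the labels and the series design text. The submitters' processing notes name STAR 2.4.0j and Cuffdiff 2.0.2, and per the design text the reads were aligned to the authors' own genome assembly. The deposited annotation gives coordinates on that assembly, with 18 nuclear scaffolds of 189.7 Mb, a plastome with 76 genes in the table and a mitogenome with 7. Of 14354 gene identifiers in the table, 14351 had a gene model and 3 did not, and 3449 had a name, which is the only source of gene names used here. The models hold coding sequence only (98.5% of nuclear coding lengths are multiples of 3), so lengths are coding lengths. Whether the flasks came from separate precultures is not given in the sources used here, so p-values measure the spread between these flasks.

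FPKM values are not counts, so no count model was used. The total reads per library were not used here. FPKM of genes of at least 400 nt times coding length was examined for low values, in bins 1% wide. With the coding length shortened by up to 300 nt in steps of 5 nt, between 11.9% and 31.6% of low values fell in the most crowded bin, where an even spread would give 0.435%. In both replicate 3 libraries the clustering appeared only with the length shortened by 205 nt (25.4% and 31.6%, against 1.72% and 3.04% with the full length), whereas in the other 4 libraries it was also present with the full length (11.6% to 18.9%). The low values therefore give rough relative depths at most, and reads were not recovered for most genes. If a step is 1 read, low values in the 1.5 µM replicate 3 library rest on the fewest reads.

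The analysis was fixed before the data were examined, except where stated. FPKM values were taken as log2(FPKM + 1), with a pseudocount of 1 FPKM, and genes with a mean over the 6 libraries of at least 1 FPKM were tested, which left 11273. A fold change on this scale understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a 2-fold threshold as a size limit. The 26 gene lists were defined by symbol patterns, and lists with at least 3 measured members (23) were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, and adjusted over the lists. The genes named are the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, every passed member of the iron uptake, iron storage, TIDI1 and electron carrier lists, up to 4 members with the smallest p of each other list called by camera, and genes named for FOX1, FTR1, FEA1, FRE1, TTF, TIDI1, ferredoxin, flavodoxin, FSD, MSD, CYC6 and PCY whether they passed or not, with at most 2 unnamed genes in each direction. Other members are named where a list is described. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.

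The procedure was tested on simulated data with the means and spreads of the 11273 genes and 200 changed genes. It recovered 50.7% of those changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 13 false calls among 169. These rates need not hold in the data, where 3408 genes were called. The simulated genes also varied independently, so shifts shared by many genes of a library were not covered. The labels number the replicates 1 to 3 in each group. Deviations from the group means correlated across genes between libraries of the same number at 0.24, 0.26 and 0.17, and between libraries of different numbers at -0.22 to -0.01, so the numbers were taken to pair the libraries. This pairing comes from the data and is not stated in the labels, so it stays an assumption. Deviations within a group sum to 0 for each gene, so the negative values are not evidence apart from the positive ones. The fit with the replicate as a block was an alternative.

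The alternatives were pseudocounts of 0.1 and 0.01 FPKM, no filter, a filter of 5 FPKM, scaling by median ratios, by quantiles and to equal sums, robust eBayes, eBayes without the trend, the replicate block, each library left out in turn, and camera on ranks. Chosen after seeing the data were lists amended for copy letters, organelle genes and unrelated symbols, a fit with replicates 1 and 2 only, and a fit with 1 gene per set of genes with identical values. Of the tested genes, 100 in 46 sets had the same FPKM as another gene in all 6 libraries. Of these, 13 pairs lie between 11024561 and 11384333 on scaffold_02 and between 3714305 and 4074094 on scaffold_03. Of these 100 genes 28 changed. Whether their reads could come from either copy was not checked by sequence, so their values are uncertain.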

Results

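Poly(A)-selected RNA was sequenced from the green alga Dunaliella tertiolecta, strain UTEX LB 999, a wall-less unicellular alga that tolerates high salt. The cells were vegetative and grew as shaken liquid cultures (140 rpm) in constant light at 24 °C with 2 M NaCl, either without added iron (0 µM) or with 1.5 µM added iron. Each iron level had 3 libraries from separate flasks, 6 in all, and each value is given below as a mean ± SD over n = 3 libraries in FPKM (fragments per kilobase of transcript, scaled to the number of mapped reads). The labels give 2 d of growth in one field and 3 days in another. The FPKM values of a library summed to between 808592 and 898151 at 0 µM and between 982304 and 1021467 at 1.5 µM, and between 12253 and 12509 genes had a value above 0. Read totals per library were not used here. The low FPKM values fell on steps, and if a step is 1 read the depths are 16100000, 16600000 and 20300000 reads in replicates 1, 2 and 3 at 0 µM and 16300000, 15200000 and 10300000 reads at 1.5 µM. These depths serve as a rough ranking only, since the coding length behind the steps differed. It was shortened by 205 nt in replicates 1 and 3 at 0 µM and replicate 3 at 1.5 µM, and was full in the others. Libraries of one group correlated at Pearson's r of 0.983 to 0.99 across genes, and libraries of different groups at 0.931 to 0.942. The first principal component held 74.5% of the variance and separated the iron levels, and the next held 9.2%.

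The comparison of 0 with 1.5 µM added iron asks how the transcriptome of this alga changes when no iron is supplied. Without added iron, genes for iron uptake, flavodoxin and the iron deficiency antenna protein TIDI1 rose, and 6 of 8 ferredoxin genes and genes for iron superoxide dismutase and ascorbate peroxidase fell. Most measured genes of the photosystem I core, the photosystem II antenna, tetrapyrrole synthesis and the Calvin-Benson cycle fell, as did all 35 measured genes for plastid ribosomal proteins. FLD1, which encodes flavodoxin, an iron-free flavoprotein that can stand in for ferredoxin, rose from 12.6 ± 2.46 to 9695 ± 875 FPKM (log2 fold change 9.49, SE 0.13, limma adjusted p = 2.62e-08). FDX1A, the more abundant of the FDX1 ferredoxin copies, an iron-sulfur electron carrier, fell from 5999 ± 462 to 429 ± 31.3 FPKM (log2 fold change -3.80, SE 0.08, limma adjusted p = 1.927e-07).

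Of 11273 genes tested, 3408 changed at a limma adjusted p under 0.05, 1303 of them higher and 2105 lower without added iron. A change of at least 2-fold on the log2(FPKM + 1) scale was found for 567 genes, 214 higher and 353 lower. The 3 libraries of one level lay wholly beyond the 3 of the other for 47.5% of the tested genes, where chance gives 10%. The balance of directions depended on the scaling. With the FPKM sums set equal the median of all genes moved from -0.03 to 0.17 on the log2 scale, and 3189 genes were higher and 1086 lower, with 323 and 227 past 2-fold. The low values stepped differently in both replicate 3 libraries than in the other 4, and with replicates 1 and 2 only, a setting chosen after seeing the data, 1685 genes changed (549 higher and 1136 lower) and 547 changed at least 2-fold. Of the fits without 1 library, the fewest genes were higher without 0 µM replicate 2 (795 higher and 1575 lower) and without 1.5 µM replicate 3 (855 and 1526). Replicate 3 alone has 1 library per level and gives no test.

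**Figure D1:**
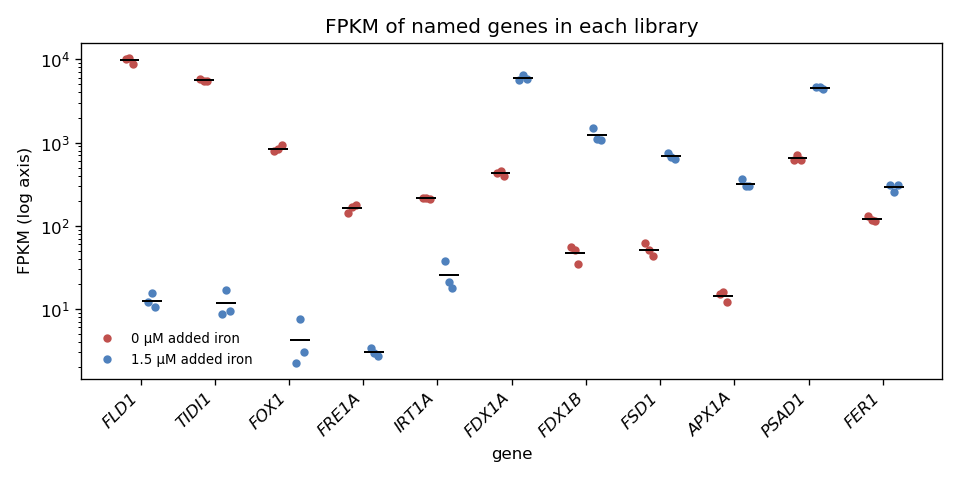
FPKM on a log axis of 11 named genes in each library, with 3 points per iron level (red, 0 µM; blue, 1.5 µM) and a black bar at their mean. FLD1, TIDI1, FOX1, FRE1A and IRT1A lie higher without added iron, and FDX1A, FDX1B, FSD1, APX1A, PSAD1 and FER1 lie lower, with no overlap between the groups.

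The largest rises among genes whose libraries did not overlap included CREG1A (log2 fold change 10.06) and SUTP1 (9.68), which lie next to each other on scaffold_02 from 15598372 to 15602295 and from 15602695 to 15609944. CREG1A went from 2.38 ± 1.04 to 3508 ± 320 FPKM and SUTP1 from 1.38 ± 0.081 to 1949 ± 131 FPKM (limma adjusted p = 1.389e-07 and 1.613e-09). SUTP3, on scaffold_01, rose from 0.126 ± 0.056 to 287 ± 28.8 FPKM. CDJ4, which encodes a chloroplast DnaJ-like protein, rose by 6.74 on the log2 scale. Some of these 10 genes have no name in the annotation, of which Dte_g14165 rose to 3235 ± 331 FPKM (log2 fold change 9.76) and Dte_g01071 to 1467 ± 125 FPKM (8.41). Among the 10 largest falls were APX1A, an ascorbate peroxidase, which is a heme enzyme (321 ± 37.5 to 14.4 ± 1.89 FPKM, log2 fold change -4.39), and FDX1B (1223 ± 243 to 47.2 ± 10.96 FPKM, -4.68). The unnamed Dte_g07239 fell from 3990 ± 256 to 62.9 ± 24.3 FPKM (-6.05) and Dte_g06025 from 394 ± 21.3 to 11.2 ± 3.08 FPKM (-5.05).

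Both members of the fixed iron uptake list rose, with the same count adjusted over the list alone. No gene carried the symbol FTR1, FEA1 or TTF in the annotation, so the list covers none of these. FOX1, a multicopper ferroxidase that oxidizes ferrous iron at the cell surface, rose from 4.26 ± 2.86 to 848 ± 78.8 FPKM (log2 fold change 7.46, SE 0.33, limma adjusted p = 5.254e-06), and lies on scaffold_09 from 5199388 to 5211892. NRAMP4, a metal transporter, rose by 1.75. When symbols with a copy letter were let in, a choice made after the names were seen, 6 of 6 members rose (camera adjusted p = 1.881e-08; adjusted p = 0.1156 with an estimated correlation), among them the ferric reductases FRE1A (log2 fold change 5.35, limma adjusted p = 1.712e-07) and FRE1B (1.97, limma adjusted p = 4.365e-06) and the transporter genes IRT1A (3.10) and IRT1B (2.54). The single iron storage gene, FER1 for ferritin, fell from 291 ± 30.7 to 121 ± 9.01 FPKM (log2 fold change -1.26, limma adjusted p = 8.831e-05). TIDI1, an LHC-family protein known from iron-starved Dunaliella thylakoids, rose from 11.8 ± 4.61 to 5620 ± 215 FPKM (8.84, SE 0.22, limma adjusted p = 3.878e-07). These lists hold 1 or 2 genes and were too small for a set test.

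Of 19 measured genes for photosynthetic electron carriers and the cytochrome b6f complex, 3 rose, 11 fell and 5 did not pass (3 and 12 adjusted over the list alone; camera adjusted p = 0.00631; adjusted p = 0.45 with an estimated correlation). Besides FLD1, the genes that rose were PGR5 (log2 fold change 0.72) and PGRL1 (0.50), which take part in cyclic electron flow. The genes that fell included PETO1 (-2.69), PETC1 for the Rieske iron-sulfur protein (-1.92), PETM1 (-1.90) and PETN1 (-1.63) of the b6f complex, the ferredoxins FDX4 (-2.38), FDX11 (-2.26), FDX6 (-1.16) and FDX7 (-0.42), and PCY1 for the copper protein plastocyanin (-0.62). FDX7 lost its call with equal sums and with replicates 1 and 2 only. FDX3 (-0.12, limma adjusted p = 0.5015) and FDX8 (-0.02, limma adjusted p = 0.9112) did not pass. FNR1, ferredoxin-NADP reductase, fell by 0.60 on the log2 scale, but was 0.10 higher under quantile normalization. CYC6, a heme-containing alternative to plastocyanin, went from 533 ± 285 to 147 ± 61.8 FPKM and passed narrowly (-1.76, limma adjusted p = 0.04404). That call was lost without either of 0 µM replicate 1 (adjusted p = 0.1254), 2 (0.06187) or 3 (0.08098) and without 1.5 µM replicate 2 (0.1048) or 3 (0.1236). It was also lost in other settings, at adjusted p from 0.05119 without the trend to 0.187 with replicates 1 and 2 only.

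All 9 nuclear genes measured for photosystem I core subunits fell, with log2 fold changes from -1.91 to -3.12, and the plastome genes psaB (-0.22, limma adjusted p = 0.6489) and psaC (0.80, limma adjusted p = 0.3801) did not pass. For the list, 9 of 11 fell, also adjusted over the list alone (camera adjusted p = 2.204e-09; adjusted p = 0.1852 with an estimated correlation). PSAE1 fell from 6433 ± 335 to 742 ± 81.8 FPKM (-3.12), PSAD1 from 4554 ± 141 to 650 ± 56.1 (-2.81), PSAF1 from 4085 ± 112 to 703 ± 30.4 (-2.54) and PSAI1 from 3969 ± 184 to 745 ± 39.8 (-2.41). In the photosystem I antenna, LHCA3 (-2.93) and LHCA2 (-2.09) fell, and 3 of 5 members did not pass, also adjusted over the list alone (camera adjusted p = 0.01334; adjusted p = 0.4591 with an estimated correlation). That call was lost under quantile normalization (camera adjusted p = 0.6846) and on ranks (0.05904). The list's median of -0.18 was 0.12 under quantile normalization and 0.05 with equal sums. That list left out the lettered copies LHCA9A (-2.28) and LHCA9B (-2.18). With them, a choice made after the names were seen, 4 of 7 LHCA genes fell, with a median of -2.09 (camera adjusted p = 0.000119; adjusted p = 0.3343 with an estimated correlation), which was -1.73 under quantile normalization and -1.86 with equal sums. LHCA1 (-0.18, limma adjusted p = 0.1327) and LHCA8 (-0.14, limma adjusted p = 0.2034) passed with the replicate as a block (adjusted p = 0.02717 and 0.0483). LHCA1 also passed without 0 µM replicate 2 (0.02743), and LHCA8 was 0.16 higher under quantile normalization.

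Of 9 measured LHCB genes of the photosystem II antenna, 8 fell, also adjusted over the list alone (camera adjusted p = 4.296e-07; adjusted p = 0.262 with an estimated correlation), among them LHCBM5 (6414 ± 453 to 1710 ± 121 FPKM, log2 fold change -1.91), LHCBM4 (-1.80), LHCB4 (-1.57) and LHCB5 (-1.42). Of 22 photosystem II subunits 10 fell and none rose (13 and 0 adjusted over the list alone; camera adjusted p = 0.0006942; adjusted p = 0.1852 with an estimated correlation), among them PSBQ1 (-1.57), PSBX1 (-1.44), PSBP3 (-1.23) and PSBR1 (-1.02). By its symbol pattern this list also held the plastome genes psbA, psbB, psbC, psbD, psbE, psbH, psbM, psbT and psbZ, which did not pass over all genes. The genes that fell were therefore nuclear. The pattern left out the plastome gene psb30, also named for photosystem II, which rose by 6.24 (limma adjusted p = 0.0005992) and is described below. Among 10 photoprotective LHC-like genes 6 fell, including OHP1 (-0.71), PSBS1 (-0.58), ELIP8 (-0.58) and ELIP7 (-0.51, not called with replicates 1 and 2 only), and 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.02925; adjusted p = 0.4001 with an estimated correlation). This call was lost without 0 µM replicate 3 (camera adjusted p = 0.06283) and with the list amended after the names were seen (0.05367). Of 24 genes of tetrapyrrole synthesis, the pathway to chlorophyll and heme, 19 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 5.474e-10; adjusted p = 0.1852 with an estimated correlation). POR1, protochlorophyllide reductase, fell from 379 ± 14.3 to 115 ± 2.34 FPKM (-1.72). CPX1, coproporphyrinogen oxidase (-1.69), CHL27, a diiron cyclase subunit (-1.48), and CHLH1 of magnesium chelatase (-1.39) fell as well.

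**Figure D2:**
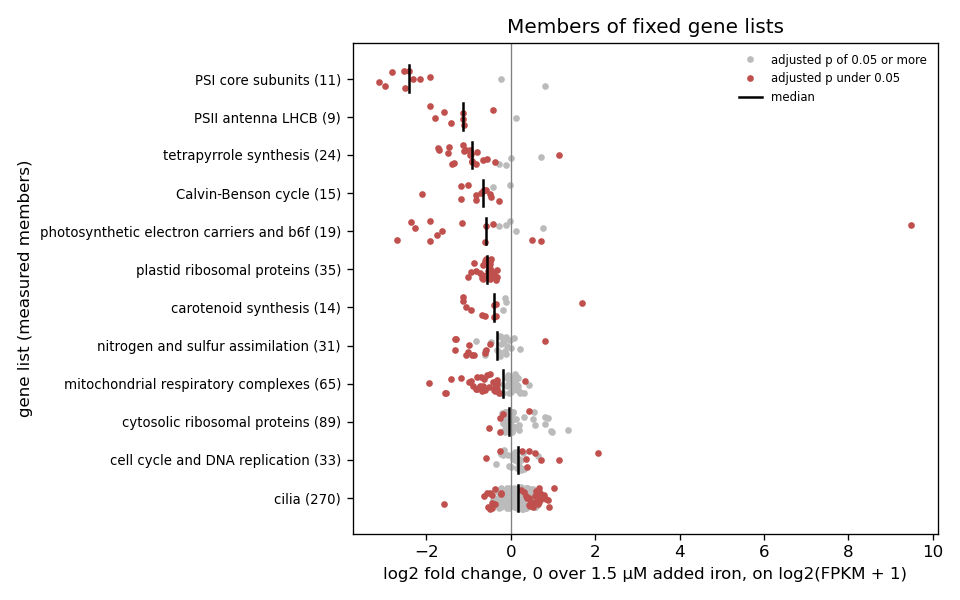
Log2 fold change (0 over 1.5 µM added iron, on log2(FPKM + 1)) of each measured member of 12 fixed gene lists, with the number of members beside each list name. Red points passed an adjusted p of 0.05, grey points did not, and the black line is the list's median, which lies at -2.41 for the photosystem I core and at 0.17 for cilia.

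All 35 plastid ribosomal protein genes fell, also adjusted over the list alone, with a median log2 fold change of -0.57 (camera adjusted p = 3.203e-14; adjusted p = 0.2837 with an estimated correlation). The median was -0.35 under quantile normalization and -0.34 with equal sums. PRPS1 fell from 295 ± 7.71 to 152 ± 3.81 FPKM (-0.95), and PRPS5 (-0.88), PRPS20 (-0.82) and PSRP7 (-0.66) fell as well. Of 15 Calvin-Benson cycle genes 13 fell, also adjusted over the list alone (camera adjusted p = 1.362e-07; adjusted p = 0.1852 with an estimated correlation), such as RPE1, ribulose-phosphate epimerase (559 ± 26.0 to 128 ± 8.18 FPKM, -2.12), PGK1 (-1.18), PRK1 for phosphoribulokinase (-1.02) and RCA1 for Rubisco activase (-0.66). Among 14 genes of carotenoid synthesis 10 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0005904; adjusted p = 0.1852 with an estimated correlation). Phytoene synthase PSY1 (-1.13), lycopene epsilon-cyclase LCYE1 (-1.12), zeaxanthin epoxidase ZEP1 (-1.06) and the cytochrome P450 gene CYP97C3 (-0.93) fell. The gene that rose, CHYB1, had the largest change of the list (27.5 ± 11.7 to 86.4 ± 9.15 FPKM, 1.69, limma adjusted p = 0.003073). In the carbon concentration list 7 of 21 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.02369; adjusted p = 0.45 with an estimated correlation). The carbonic anhydrase genes CAH4 (493 ± 138 to 98.3 ± 28.3 FPKM, -2.32) and CAG1 (-0.96) and the LCI8 gene (-0.81) fell, and LCI20 rose by 0.61. The list's call was lost without 0 µM replicate 3 (adjusted p = 0.07699).

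Of 31 genes of nitrogen and sulfur assimilation 11 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.0002565; adjusted p = 0.1852 with an estimated correlation). Sulfite reductase SIR1 (-1.32) and ferredoxin-dependent glutamate synthase GSF1 (-1.31), which draw electrons from ferredoxin, fell, as did glutamine synthetase GLN2 (-1.05) and the ammonium transporter AMT1A (-1.01). For glycerol metabolism, which supplies the osmolyte of Dunaliella, 4 of 5 genes fell, also adjusted over the list alone (camera adjusted p = 0.007666; adjusted p = 0.1852 with an estimated correlation), with GPD3 for glycerol-3-phosphate dehydrogenase at -1.13, dihydroxyacetone kinase DAK1 at -1.03, GPD4 at -0.49 and GPD1 at -0.42. With equal sums GPD1 and GPD4 were no longer called, nor was GPD1 with replicates 1 and 2 only. Of 65 genes of the mitochondrial respiratory complexes 30 fell and 1 rose (31 and 1 adjusted over the list alone; camera adjusted p = 0.0008452; adjusted p = 0.5658 with an estimated correlation). The 4 members with the smallest p were NUOAF4 (-1.94) and NUO7 (-0.99) of complex I and SDH2 (-1.55) and SDH3 (-1.53) of succinate dehydrogenase. The list's call was lost under quantile normalization (camera adjusted p = 0.08488), and its median of -0.19 was 0.04 with equal sums.

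Of 21 antioxidant enzymes 4 rose and 8 fell, also adjusted over the list alone, and camera made no call (camera adjusted p = 0.2874; fry adjusted p = 0.01172). The largest rise in the list was that of MDAR1 (1.72, limma adjusted p = 3.594e-06). This list left out the lettered ascorbate peroxidase copies APX1A (-4.39) and APX1B (-2.18). With them, a choice made after the names were seen, 4 of 23 rose and 10 fell (camera adjusted p = 0.05874, and 0.6289 with an estimated correlation). FSD1 for iron superoxide dismutase fell from 681 ± 57.2 to 51.7 ± 9.30 FPKM (-3.70, SE 0.13, limma adjusted p = 2.164e-06) and FSD2 from 34.1 ± 1.64 to 10.1 ± 1.07 FPKM (-1.67). The manganese enzymes MSD1 (0.01, limma adjusted p = 0.9613) and MSD2 (0.04, limma adjusted p = 0.7952) did not pass, and both passed with equal sums (0.23 and 0.27 higher). Of 20 genes in the list of iron-sulfur cluster assembly 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.5326; fry adjusted p = 0.005603). By its symbol pattern this list also held genes with unrelated symbols. Amended for these and for copy letters, a choice made after the names were seen, it had 3 of 18 rising and 5 falling (camera adjusted p = 0.3982, fry adjusted p = 0.005539). Members went both ways for copper and zinc homeostasis (4 of 25 rose and 6 fell, also over the list alone; camera adjusted p = 0.6743). That list also held genes with the unrelated symbol COG. Amended in the same way, it had 5 of 25 rising and 7 falling (camera adjusted p = 0.7484). Chaperones included 4 of 32 that rose and 10 that fell (4 and 13 adjusted over the list alone; camera adjusted p = 0.3315). For storage lipid 2 of 7 rose and 1 fell, also over the list alone (camera adjusted p = 0.6665).

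The cilia list was higher without added iron by camera, with 29 of 270 members rising and 13 falling (11 and 5 adjusted over the list alone), a median of 0.17 on the log2 scale and camera adjusted p = 0.0001881, but adjusted p = 0.7181 with an estimated correlation. The median was 0.07 without 1.5 µM replicate 1 and 0.38 with equal sums. TUB2 for tubulin rose from 652 ± 10.9 to 1229 ± 107 FPKM (0.91), and FAP333 rose by 0.67, while FAP269 (-1.59) and FAP131 (-0.64) fell. The 34 members with at least 4800 nt of coding sequence had a median of -0.17. For the cell cycle and DNA replication list 8 of 33 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.007666; adjusted p = 0.5612 with an estimated correlation), including the ribonucleotide reductase genes RIR2A (2.06) and RIR2B (1.15), CDC20 (0.58) and CDKB1 (0.43). RIR2B and CDKB1 were not called with replicates 1 and 2 only. Of 89 genes in the list of cytosolic ribosomal proteins 1 rose and 4 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.6665), and the list was called higher under quantile normalization (camera adjusted p = 7.872e-14) and with equal sums (1.295e-07) and lower without 0 µM replicate 2 (0.01925). By its symbol pattern this list also held organelle genes, such as rps18 (1.36, limma adjusted p = 0.1243) and rps12, which fell by 0.52 on the log2 scale. Without organelle genes, a choice made after the names were seen, 1 of 74 rose and 3 fell, with log2 fold changes from -0.25 to 0.42 (camera adjusted p = 0.3088). Genes of the sexual cycle, included as markers of another cell state, showed 2 of 6 falling and none rising, also over the list alone (camera adjusted p = 0.4066; fry adjusted p = 0.01304).

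With the preset correlation of 0.01, camera called 16 of 23 lists, 2 higher and 14 lower. With a correlation estimated from these 6 libraries it called 0, with 4 lists at an unadjusted p under 0.05. In that setting camera takes its degrees of freedom from the libraries and not from the genes, so calls are hard to reach for any list. By fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 17 of the 23 lists passed. These included antioxidant enzymes, iron-sulfur cluster assembly and the sexual cycle, which camera did not call, and left out cilia (fry adjusted p = 0.4564) and the cell cycle list (0.1335), which it did. Median and mean differed in sign for chaperones (-0.15 and 0.10), storage lipid (-0.06 and 0.09) and the fixed list of cytosolic ribosomal proteins (-0.04 and 0.04), where camera pointed down, up and down. Without its organelle genes the latter had a median and a mean of -0.05.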

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

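The tests on replicates 1 and 2 only, on amended lists and on genes with identical values were chosen after the data were seen. The count of genes changed at least 2-fold stayed between 515 and 682 under all alternatives, and the count of changed genes between 2370 and 4275 except with replicates 1 and 2 only (1685 changed, 549 higher and 1136 lower), where fewer libraries were fitted. Leaving out a library gave 795 to 1288 higher genes, the lowest without 0 µM replicate 2 (795) and without 1.5 µM replicate 3 (855). With equal sums 3189 genes were higher and 1086 lower (323 and 227 past 2-fold), since this scaling raises every 0 µM value. Counting 1 gene per set with identical values left 3393 changed genes. The replicate block gave 3973 changed genes, 1611 higher and 2362 lower, and 591 past 2-fold, kept 3298 of the 3408 calls and changed no other call among the lists and named genes than those of LHCA1 and LHCA8. Camera with an estimated correlation ended all 16 list calls, at adjusted p of 0.1852 (photosystem I core, photosystem II subunits, tetrapyrrole, Calvin-Benson, carotenoid, glycerol, nitrogen and sulfur), 0.262 (LHCB), 0.2837 (plastid ribosome), 0.4001 (photoprotective), 0.45 (electron carriers, carbon concentration), 0.4591 (LHCA), 0.5612 (cell cycle), 0.5658 (respiratory complexes) and 0.7181 (cilia). The estimated correlation lay below the preset 0.01 for the carotenoid (-0.017) and the nitrogen and sulfur list (0.007). A higher correlation within these lists therefore does not account for their lost calls. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, and with a preset one from the genes. The lost calls alone therefore do not measure correlation within a list. Under quantile normalization the LHCA (0.6846) and respiratory (0.08488) calls were lost, the cytosolic ribosome list was called higher (7.872e-14; with equal sums 1.295e-07), and FNR1 (0.10) and LHCA8 (0.16) changed sign. The LHCA call was also lost on ranks (0.05904) and the photoprotective one with amended lists (0.05367). Without 1 library, adjusted p ranged from 0.01335 to 0.06283 for the photoprotective list, from 0.01081 to 0.07699 for carbon concentration and from 0.01925 to 0.9212 for the cytosolic ribosome. The cause was not tested where none is given. Of the values of named genes under the alternatives, 1829 kept direction and side of the threshold, 18 lost the call, 5 gained one and 2 changed sign. What depth limits is known only as far as a step in the low values is 1 read, which would put 1.5 µM replicate 3 lowest.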

Other observations

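All tests in this part were chosen after the result was seen. Named nuclear genes were grouped by the letters of their symbols into 101 families of at least 6 members, of which camera called 27 at an adjusted p under 0.05 and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Outside the fixed lists 15 families were called, 13 higher and 2 lower. Subunits of adaptor protein complexes (AP) rose in 7 of 11 cases and fell in none, with a median log2 fold change of 0.48 (camera adjusted p = 1.499e-05; adjusted p = 0.7334 with an estimated correlation), among them AP2S2 (1.64), AP1G1 (0.87) and AP1M1 (0.70). Vacuolar protein sorting genes (VPS) rose in 7 of 27 cases, with a median of 0.22 (camera adjusted p = 0.0002839; adjusted p = 0.7334 with an estimated correlation), such as VPS5A (0.63) and VPS26 (0.50). Alpha subunits of the 20S proteasome (POA) rose in 5 of 7 cases, with a median of 0.24 (camera adjusted p = 0.005113; adjusted p = 0.7334 with an estimated correlation). The lower ones were EFG, with 6 of 11 falling, none rising and a median of -0.41 (camera adjusted p = 0.01022; adjusted p = 0.7334 with an estimated correlation), and TEF, with 4 of 8 falling, 1 rising and a median of -0.38 (camera adjusted p = 0.04896; adjusted p = 0.7334 with an estimated correlation). With equal sums the medians of AP, VPS, POA, EFG and TEF were 0.71, 0.43, 0.47, -0.18 and -0.15, and each kept its sign under each scaling tried. Of the 7 mitogenome genes 2 fell and none rose, with a median of -0.77.

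The real split gave 3408 changed genes and 567 past 2-fold, and no other of the 10 splits of the 6 libraries into 3 and 3 gave more than 2 and 2. Only 1 of 10 splits, the real one, reached each count, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 numbered pairs called 0 genes, and they differ from the real one in mixing iron levels within a group.

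Plastome genes had a median log2 fold change of 0.40 over 49 genes (95% bootstrap interval over genes 0.17 to 0.62), with 5 rising and 1 falling. The plastome took 2.24% of the FPKM sum in 0 µM replicate 1 and between 0.385% and 0.536% in the other 5 libraries. Short coding sequences as the whole cause are argued against, since the 38 plastome genes of at least 300 nt had a median of 0.44 (0.16 to 0.60). Carry-over of organelle RNA through poly(A) selection in that 1 library may account for the shift, since without it the median was 0.02 (-0.25 to 0.21). The gene psb30, named after its values were seen, was at 357, 115 and 47.6 FPKM at 0 µM and at 0.6, 1.9 and 0 at 1.5 µM, so all 3 libraries at 0 µM lay above all 3 at 1.5 µM.

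The cilia list was higher at 0 µM (median 0.17 over 270 genes, 0.38 with equal sums), although its median deviation was -0.08, 0.20 and 0.15 in replicates 1 to 3 at 0 µM and -0.32, 0.13 and -0.07 at 1.5 µM. Over all tested genes the median log2 fold change went from 0.07 below 300 nt of coding length to -0.19 from 4800 nt on. Length as the cause of the list's median is argued against, since lists of other genes matched on coding length had a median of -0.06. None of 10000 draws reached the cilia median, a share of 0.01% with the cilia list itself counted. That share may be too small, since the draws took genes singly while cilia genes varied together (estimated correlation 0.547). The shift does not extend to long genes, since the 34 cilia genes from 4800 nt on had a median of -0.17, and of the 15 DHC genes, all in the list, 4 fell and none rose (median -0.29, camera adjusted p = 0.04031; adjusted p = 0.8351 with an estimated correlation). Of all 673 tested genes from 4800 nt on, 26.3% fell and 3.4% rose. Camera compared the DHC genes with genes of all lengths. Within the numbered pairs the median difference was 0.23, 0.06 and 0.22, higher at 0 µM in each. A low value in 1.5 µM replicate 1 may account for part of the shift, since without it the median was 0.07 (0.03 to 0.10), and the 2 pairs left are too few to exclude it, so the iron level stays open.

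Histone genes were higher at 0 µM, with 11 of 37 rising and none falling and a median log2 fold change of 0.72 (0.47 to 0.96 over genes), among them HON4 (1.89), HON3 (1.84), HTB3 (1.48) and HTB1 (1.32), which encode linker histones and H2B. By family, 4 of 6 HON and 3 of 6 HTB genes rose (camera adjusted p = 0.01383 and 0.005113, and 0.7703 and 0.7334 with an estimated correlation). HTA, with 0 of 12 rising and a median of 0.45, and HFO, with 1 of 8 and 0.60, were not called (camera adjusted p = 0.09418 and 0.06382). The histone median exceeded that of the cell cycle list by 0.56 (0.28 to 0.80 over genes). That interval draws genes singly and does not measure the spread between libraries. It therefore does not decide whether all cell cycle genes rose by the same size. A shared rise, of equal or unequal size, stays open, since the cell cycle list was also higher (median 0.17, 0.09 to 0.24) and included RIR2A at 2.06. Carry-over of RNA without a poly(A) tail in 0 µM replicate 1 is argued against, since without that library the histone median was 0.67 (0.47 to 0.95). Its median deviation of 0.35 also lay below that of replicate 2 (0.58). A low value in 1.5 µM replicate 3 (-0.94) cannot be told apart from an effect of the iron level, since without it the median was 0.42 (0.17 to 0.56) and 2 pairs are left. The median difference within pairs was 0.33, 0.79 and 1.01, higher at 0 µM in each. In HAV2A and HAV2B, the most abundant members, 1.5 µM replicate 3 lay near its group. HAV2A was at 335, 392 and 349 FPKM at 0 µM and 191, 204 and 184 at 1.5 µM (0.89, limma adjusted p = 0.00019). HAV2B was at 284, 309 and 290 against 154, 136 and 148 (1.01, limma adjusted p = 5.822e-05). This did not hold for all abundant members, since HON6 was at 50.0, 66.6 and 80.6 FPKM at 0 µM and 50.4, 48.1 and 14.1 at 1.5 µM.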
